A study of Mus musculus with 9 samples.

How the data were processed

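The deposited processed values of 9 Affymetrix mouse whole-transcript arrays were used: 3 of cells treated with DMSO, 3 with AM73 and 3 with AM80. Per the file headers the authors made log2 values in Expression Console 1.41 with RMA background correction, quantile normalization and median polish, annotated with NetAffx build 35 on mm10. Per the labels the input was 100 ng of total RNA. The deposited comparison table also holds linear group averages per the file headers in intensity units, signed folds made by the authors as a score with falls as negative folds, and the authors' p-value and q-value columns from a Student's t-test. The authors do not state how the q-value was made. Both deposited tables hold the same log2 values for each array, with a largest difference of 0. The p-values were recomputed from the linear values, and the median absolute difference from the authors' p-value was 5.05e-05, 5.12e-05 and 5.19e-05 in log10 units for the 3 comparisons.

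Of 41345 features, 33793 were gene features and 32202 of these carried a symbol, while 1591 did not. Symbols were matched to the reference table by Entrez identifier for 25099 features, and 1913 symbols were renamed. Where a symbol had several features, as 772 did, the one with the highest mean over the 9 arrays was kept. This left 30860 genes, of which 3415 have probes that the annotation gives as cross-hybridising. Of the remaining features 82 were reporter and 190 control features. No pair of the 36 pairs of arrays was identical (0 pairs).

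Gene changes were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8), on all 9 arrays in a single fit with 6 residual degrees of freedom. All tests are two-sided. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The fold changes printed are 2 to the power of the absolute log2 difference. Intervals are 95% intervals of the fit. Any difference among the 3 groups was tested with limma's moderated F-test.

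A set of 38 gene lists of 845 genes, of which 828 were measured, and the rule for naming genes were written before the data were examined. The lists cover HIF targets, glycolysis, respiratory complex I, complexes II to V, the mitochondrial ribosome, mitochondrial biogenesis, mitochondrial antioxidants, the citric acid cycle, fatty acid oxidation, thermogenic genes, PPARγ-driven fat cell genes, lipogenesis, cholesterol synthesis, LXR targets, xenobiotic receptor targets, aryl hydrocarbon receptor targets, NRF2 targets, retinoic acid targets, glucocorticoid targets, p53 targets, NF-κB targets, interferon response, integrated stress response, unfolded protein response, heat shock, proteasome, autophagy and lysosome, cytosolic ribosomal proteins, cell cycle, circadian clock, cAMP targets, immediate early genes and extracellular matrix, and markers of preadipocytes and fibroblasts, macrophages, endothelial cells, skeletal muscle and white adipocytes. Lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01 and Benjamini-Hochberg over the lists. Of the calls made, 1 held with an estimated correlation (HIF targets with AM73). Lists were also tested with fry, which asks if the genes of a list move in a common direction and does not compare them with other genes.

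Genes named are, per comparison, the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05 and groups that do not overlap, without genes whose symbols mark them as predicted genes, microRNA, small nucleolar RNA, ribosomal RNA, olfactory or vomeronasal genes (Gm with a number, Rik, Mir, Snor, n-R, LOC, Olfr and Vmn). Symbols of mitochondrial tRNA genes are not among these. Ppargc1a, Ppargc1b, Ucp1, Cidea, Dio2, Pparg, Esrra, Fgf21, Cycs and Cpt1b are always named. Of each list that was called or had at least 3 members past the threshold, up to 4 members with the smallest adjusted p are named. A few other list members are given where another comparison names them.

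The alternatives fixed beforehand were a filter on dim genes (above the 40th percentile, 18508 genes), all clusters of a gene, quantile normalization again, centring on the median, only the groups compared, a replicate block, an ordinary linear model, trend and robust moderation, array weights, a fold of at least 1.5, the authors' deposited q-value, an estimated correlation, fry, and leaving out each array. Alternatives added after the values were seen were the plate column as a block, each plate column alone, a covariate from the mean of the 6 brightest antigenomic probe sets, scaling to poly-A controls, leaving out 2 arrays of low weight, and the methods' t-test on the same genes. The plate column was inferred from the number at the end of the array column names, which no label explains. Shared controls were simulated 100 times with unchanged groups. Gene span is the distance from first to last base of a gene in the reference table, or by the array annotation's coordinates where stated, which can differ. For each list, brighter genes (above the 40th percentile) of the span bins of its members were set beside the list median, a comparison added after the lists were seen.

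A self-test used simulated arrays, with independent noise around each gene's mean and changes of known size added to 50 genes per fold. These arrays hold no effects common to an array, so the shares found may not hold for the real ones. The fit recovered 76% of 2-fold changes for AM73 against DMSO, 80% for AM80 against DMSO and 84% for AM80 against AM73. Of 1.5-fold changes it recovered 16%, 12% and 10%. False calls numbered 5, 2 and 11. Raw probe files were not used here, so probe-level background and RNA integrity were not analysed here.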

Results

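RNA of mouse brown fat cells in culture (C57BL/6, fully differentiated) was measured on whole-transcript arrays after 8 h with 10 µM of either of 2 compounds, AM73 or AM80, or with the solvent DMSO alone. Each group holds 3 arrays, 9 in all, and the labels call the replicates technical, so the p-values below measure only the spread between these arrays. The labels do not say if the 3 arrays of a group come from separate wells or from 1 RNA, so a group may hold a single sample. The number of arrays limits the precision. Values are log2 expression values of 30860 genes, 1 transcript cluster per gene, with array medians between 2.75 and 2.89. Correlations between arrays of a group, taken across genes, which are not independent replicates, ran from 0.982 to 0.992.

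The AM80 arrays stood apart from the others in more than the genes. On the first principal component, which held 58.7% of the variance, they lay at 74.7, 53.7 and 31.2, DMSO replicate 3 lay at 2.51, and the other 5 arrays lay between −41.6 and −22.6. The poly-A spike-in controls, RNAs added to each sample before labelling, had a median of 5.50 ± 0.33 with AM80, 4.66 ± 0.16 with DMSO and 4.37 ± 0.30 with AM73 (SD, n = 3). The 6 brightest antigenomic background probe sets, which match no mouse gene, averaged 5.91 ± 0.21 with AM80, 5.04 ± 0.49 with AM73 and 5.58 ± 0.37 with DMSO (SD, n = 3). All 3 AM80 arrays lay above all 3 AM73 arrays there. A fit with these probes as a covariate therefore cannot fully tell background from the difference between the compounds. The intron and exon control features of the array had mean medians of 2.44 and 6.91 with AM80, 2.61 and 7.10 with DMSO, and 2.76 and 7.145 with AM73. On DMSO replicate 3 they were 2.49 and 6.99, the lowest of the DMSO arrays, and the cause was not tested. Scaling each array to the poly-A controls moved the median of all genes by 0.287 with AM73, by −0.84 with AM80, and by −1.13 between AM80 and AM73. Every rise and fall below is therefore a change relative to the bulk of genes on the same array. The array column names end in a letter and a number, read here as a plate position, which the labels do not state. By that reading all 3 AM80 arrays lie in plate column 5, with DMSO replicate 2 and AM73 replicate 2, and the other 4 arrays in column 7. Values with the column as a term of the fit, and within a column, are given for counts, lists and the genes read first. For other named genes they are given where a call was lost with the column as a term. Column 7 holds no AM80 array.

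The series title names the compounds as activators of PGC-1α, the coactivator of mitochondrial and heat-producing genes, so its gene Ppargc1a and the uncoupling protein gene Ucp1 were read first. Ppargc1a (cluster 17448001, mm10 chromosome 5, 51454249 to 51567725, minus strand) averaged 7.06 ± 0.34 with DMSO, 6.81 ± 0.01 with AM73 and 5.40 ± 0.38 with AM80 (SD, n = 3). It fell by 1.66 ± 0.21 with AM80 (SE, adjusted p = 0.00237 and 3.15-fold). All 3 AM80 arrays lay below all 3 DMSO arrays, of which replicate 3 was the lowest (7.31, 7.19 and 6.67 on replicates 1, 2 and 3). With AM73 the change was −0.24 ± 0.21 (95% interval −0.71 to 0.22, adjusted p = 0.796). The difference AM80 minus AM73 was −1.41 ± 0.21 (adjusted p = 0.00166), with all 3 AM80 arrays below all 3 AM73 arrays. This call was lost with the bright background probes as a covariate (−1.05, adjusted p = 0.136) and within plate column 5 (−1.40, adjusted p = 0.234), and kept with the column as a term (−1.47, adjusted p = 0.0130). Ucp1 (cluster 17502899, chromosome 8, 83290348 to 83298456, plus strand) averaged 3.97 ± 0.53 with DMSO, 6.13 ± 0.44 with AM73 and 5.90 ± 0.17 with AM80 (SD, n = 3). Ucp1 rose by 2.16 ± 0.28 with AM73 (adjusted p = 0.0256, 4.48-fold) and by 1.93 ± 0.28 with AM80 (adjusted p = 0.0032, 3.82-fold), in 3 of 3 arrays each. Among the DMSO arrays Ucp1 was highest on replicate 3 (3.54, 3.8 and 4.56 on replicates 1, 2 and 3). The compounds' difference in Ucp1 was −0.23 ± 0.28 (95% interval −0.85 to 0.39, adjusted p = 0.643), an interval that leaves room for a difference in either direction.

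Other regulators of brown fat genes moved with AM80. Esrra, a nuclear receptor partner of PGC-1α, rose by 0.98 ± 0.14 (adjusted p = 0.00324). Pparg, the master regulator of fat cell differentiation, fell by 0.91 ± 0.15 (adjusted p = 0.00497). With AM73 their changes were −0.13 (adjusted p = 0.834) and 0.03 (adjusted p = 0.971). AM80 differed from AM73 by 1.11 (adjusted p = 0.00103) and −0.94 (adjusted p = 0.00217), which the background covariate ended as calls (adjusted p = 0.0947 and 0.155). The AM80 changes with the plate column as a term were 1.03 (adjusted p = 0.0274) and −0.91 (adjusted p = 0.0384). On DMSO replicate 3 Esrra was the highest of the DMSO arrays (5.17, 5.07 and 5.52 on replicates 1, 2 and 3). Pparg was the lowest there (10.3, 10.04 and 9.8). Both AM80 changes thus have the direction in which that array departs, and how much of them comes from AM80 stays open. Cpt1b, which brings fatty acids into mitochondria, rose by 0.56 with AM80 (adjusted p = 0.0414), less than the size of the poly-A shift, so under that scaling it lies below DMSO. Ppargc1b, Cidea, Dio2, Fgf21 and Cycs passed in none of the 3 comparisons, with AM80 changes of −0.04, 0.82, 0.18, 0.18 and −0.08. Dio2 lay near the background probe medians of the arrays (2.21, 1.91 and 2.27 with DMSO, against 2.07 to 2.32), so its changes are weakly measured. With the plate column as a term Ppargc1a changed by −1.72 with AM80 (adjusted p = 0.0255). Ucp1 then changed by 2.16 with AM73 (adjusted p = 0.0601) and 2.06 with AM80 (adjusted p = 0.0268). Within column 5 the 3 values were −1.79, 2.24 and 2.10 (adjusted p = 0.321, 0.843 and 0.321). Within column 7 Ucp1 changed by 2.13 with AM73 (adjusted p = 0.795). Over all alternatives the adjusted p ranged from 0.000526 to 0.321 for Ppargc1a with AM80, from 0.00558 to 0.843 for Ucp1 with AM73 and from 0.00107 to 0.321 for Ucp1 with AM80. The Ucp1 call with AM73 was lost without DMSO replicate 1 (0.120), DMSO replicate 2 (0.135), AM73 replicate 1 (0.0934), 2 (0.142) or 3 (0.108), and AM80 replicate 1 (0.0510) or 2 (0.0662). The Cpt1b call was lost with the plate column as a term (adjusted p = 0.0798), and without DMSO replicate 1 or 2, AM73 replicate 2 or 3, or AM80 replicate 1 or 3 (up to 0.139).

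**Figure D1:**
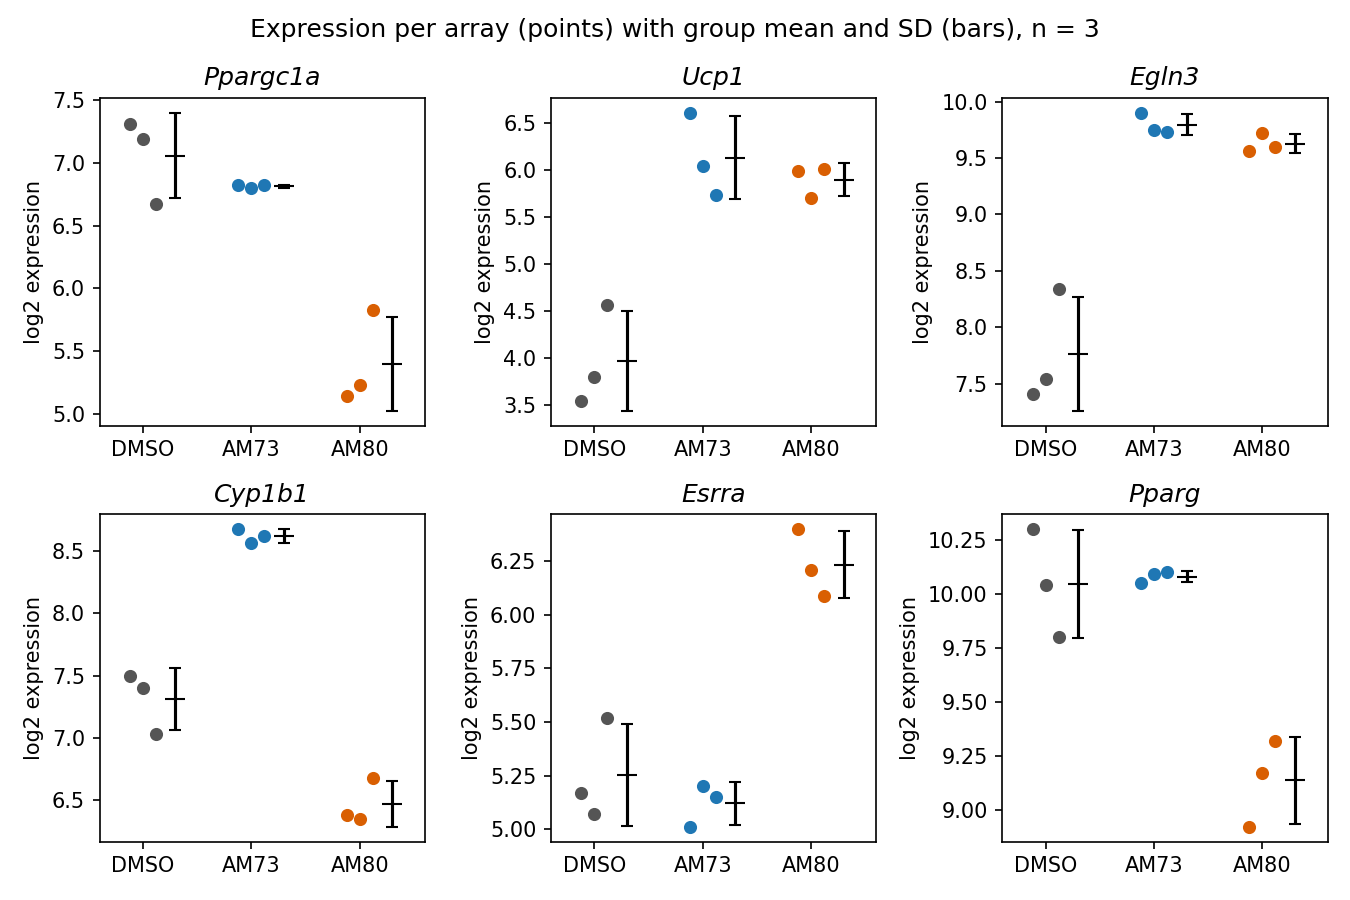
Log2 expression of Ppargc1a, Ucp1, Egln3, Cyp1b1, Esrra and Pparg on each of the 9 arrays, with the mean and SD of each group of 3. The 3 AM80 arrays lie below the DMSO arrays for Ppargc1a, Pparg and Cyp1b1, and both compounds' arrays lie above DMSO for Ucp1 and Egln3.

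AM73 against DMSO asks what this compound does to the transcriptome within hours. It raised 32 genes, of which 9 are on the list of targets of the hypoxia-inducible factor HIF, which drives genes for life at low oxygen. After Ucp1 the largest rises were in Egln3, an oxygen-sensing prolyl hydroxylase (cluster 17281084, chromosome 12, 54178981 to 54203874, 2.03 ± 0.21, adjusted p = 0.0148), the lactate exporter Slc16a3 (1.82 ± 0.23, adjusted p = 0.0244) and Ankrd37 (1.81 ± 0.26, adjusted p = 0.0438). They were followed by the AP-1 subunit Fosl1 (1.69 ± 0.18, adjusted p = 0.0165) and the histone demethylase Kdm3a (1.66 ± 0.22, adjusted p = 0.0282). Sema3g rose by 1.66 ± 0.12 (adjusted p = 0.00394), P4ha1, a collagen prolyl hydroxylase subunit, by 1.35 ± 0.11 (adjusted p = 0.00549). The fatty acid receptor gene Ffar4 rose by 1.54 ± 0.21 (adjusted p = 0.04), and Cyp1b1 (cluster 17347448, chromosome 17, 79706894 to 79715061), a target of the aryl hydrocarbon receptor, by 1.31 ± 0.14 (adjusted p = 0.0165). Of the 5 genes that fell, 2 are predicted genes that the naming rule leaves out, the steepest fall (−1.34) among them. The others are the mitochondrial tRNA gene mt-Tm (−1.21), Tcp10a (−0.98) and the histone gene H2bc4 (−0.82), with adjusted p of 0.0282, 0.0165 and 0.0243. Tcp10a has probes given as cross-hybridising, and its mean went from 2.83 with DMSO to 1.86 with AM73, below the background probe medians of the arrays (2.07 to 2.32), so its fall is weakly measured. In all, 37 genes passed in limma, 32 higher and 5 lower, each with all 3 AM73 arrays beyond all 3 DMSO arrays. Of all tested genes 12.6% had groups that did not overlap, where chance gives 10%.

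With the plate column as a term 18 genes passed. Within column 5, 1 array against 1 array, and within column 7, 2 against 2, limma called 0 genes, with 1772 and 1804 at an unadjusted p under 0.05. With the bright background probes as a covariate 11 passed. Each AM73 call was lost in at least 1 fit that left out an array. Without DMSO replicate 1, limma called 0 genes (2547 at an unadjusted p under 0.05), and without DMSO replicate 2 it called 1 gene. Without AM73 replicate 1, 2 or 3 it called 3, 2 and 3, and without AM80 replicate 2 it called 2. Sema3g missed the threshold only without DMSO replicate 1 (adjusted p = 0.0511), and P4ha1 only without DMSO replicate 1 or 2 (up to 0.0724). Egln3, Slc16a3, Fosl1, Cyp1b1, P4ha2, Pdk1 and Tcp10a passed in the fits without DMSO replicate 3, AM80 replicate 1 or AM80 replicate 3. In the other 6 fits their adjusted p rose to 0.108, for Pdk1 to 0.120 and for Slc16a3 to 0.142. Their changes kept their sign in all 9 fits, from 1.85 to 2.32 for Egln3, 1.55 to 2.08 for Slc16a3 and 0.90 to 1.05 for Pdk1. Kdm3a passed without DMSO replicate 3 or AM80 replicate 3 (elsewhere up to 0.180), mt-Tm without DMSO replicate 3 or AM80 replicate 1 (up to 0.173), and H2bc4 without AM80 replicate 1 or 3 (up to 0.142). Those that passed only without DMSO replicate 3 were Ankrd37, Ffar4 and Bhlhe40 (elsewhere up to 0.214, 0.214 and 0.186). With the plate column as a term Slc16a3, Kdm3a, Ankrd37, Ffar4, mt-Tm and Bhlhe40 missed the threshold (adjusted p = 0.0601, 0.0601, 0.0957, 0.0936, 0.0584 and 0.0906). DMSO and AM73 each have 1 array in column 5 and 2 in column 7. The term therefore leaves each AM73 change against DMSO as it was and alters only its precision. The other named genes but Ucp1 passed, with adjusted p between 0.0136 and 0.0455. The methods' t-test, run on the same genes, called 3 genes, none of them among the 37.

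Among the gene lists fixed beforehand, HIF targets rose most clearly with AM73. Of 21 measured members 9 rose and 0 fell, 19 when adjusted over the list alone. The list median was 0.98 (adjusted p = 1.15e-42 in camera, and adjusted p = 0.0153 with an estimated correlation). Next to Egln3, Ankrd37, Kdm3a and P4ha1, its members include P4ha2 (1.19) and Pdk1 (0.97), which passed. The glucose transporter gene Slc2a1 (1.28) and Vegfa (0.56) did not pass, with adjusted p of 0.0569 and 0.0927. The list passed with the plate column as a term, which cannot move its median (0.98), and within column 7 (0.93). Within column 5, with 1 array of each group and the spread taken from the AM80 arrays, its median was 1.08, a value that adds little support to the call. Over all alternatives its adjusted p ranged from 3.49e-54 to 0.0153. Glycolysis genes, which supply ATP without oxygen, had a median of 0.39 over 17 members (adjusted p = 8e-13, and adjusted p = 0.135 with an estimated correlation). Of these only Slc16a3 rose, 11 when adjusted over the list alone. It was the sole other list with a median above 0.3, and it shares Slc2a1 and Pfkfb3 with the HIF list.

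Smaller shifts were called in 12 further lists with AM73, none of which kept its call with an estimated correlation. Upward, aryl hydrocarbon receptor targets had a median of 0.26 (Cyp1b1 rose, of 8), circadian clock genes 0.14 (Bhlhe40, 0.86, rose, of 19), cAMP targets 0.08 and thermogenic genes 0.07 (Ucp1 rose in each, of 18 and 30), and heat shock genes 0.12 (0 of 18 passed). Their adjusted p were 0.0009, 0.000354, 0.0114, 0.0152 and 0.0173 in camera, and adjusted p = 0.135, 0.135, 0.300, 0.135 and 0.163 with an estimated correlation. Downward, without a single member that passed over all genes, came proteasome subunits (−0.24 over 31), respiratory complex I (−0.21 over 36), complexes II to V (−0.15 over 38), and the mitochondrial ribosome (−0.15 over 39). The others were the integrated stress response (−0.16 over 31), the citric acid cycle (−0.13 over 21) and cytosolic ribosomal proteins (−0.11 over 33), and under the poly-A scaling all 7 medians turn positive. Their camera adjusted p were 6.84e-08, 8.83e-07, 6.64e-05, 0.000214, 0.000825, 0.00371 and 0.0256, and adjusted p = 0.135, 0.345, 0.372, 0.345, 0.345, 0.301 and 0.616 with an estimated correlation. Adjusted over the list alone, 1 aryl hydrocarbon receptor target, 1 clock gene, 3 cAMP targets and 3 thermogenic genes rose, and 1 thermogenic gene and 1 stress response gene fell. In the heat shock list and the other 6 lists with lower medians 0 genes passed in limma. Complex I, complexes II to V, the mitochondrial ribosome and ribosomal proteins are lists of short genes (median spans of 3551 to 8097 bp). Brighter genes of the same span bins had AM73 medians between −0.09 and −0.06, and these 4 lists lay higher on DMSO replicate 3 than on the other DMSO arrays (0.14 to 0.24). Their downward shift thus has the direction of a span trend, and how much of it comes from AM73 stays open.

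All 14 calls held with the plate column as a term, which cannot move a list median of AM73 against DMSO, and 11 held within column 7. Within column 5, where 1 array stands against 1 and the spread comes from the AM80 arrays, 4 lists were called (HIF targets, glycolysis, complex I and proteasome). With the bright background probes as a covariate complex I, the mitochondrial ribosome, the stress response and ribosomal proteins lost theirs (adjusted p = 0.0556, 0.132, 0.0971 and 0.480). Calls were lost for cAMP targets without AM73 replicate 1 (adjusted p = 0.109), and for thermogenic genes without AM73 replicate 1 or 2 (up to 0.0698). They were also lost for heat shock genes without DMSO replicate 1 or AM73 replicate 1 (up to 0.121), and for ribosomal proteins without DMSO replicate 3, AM73 replicate 1 or AM73 replicate 2 (up to 0.557). With fry 9 of the 14 lists missed the threshold (up to 0.357), among them all lists with lower medians but the proteasome.

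**Figure D2:**
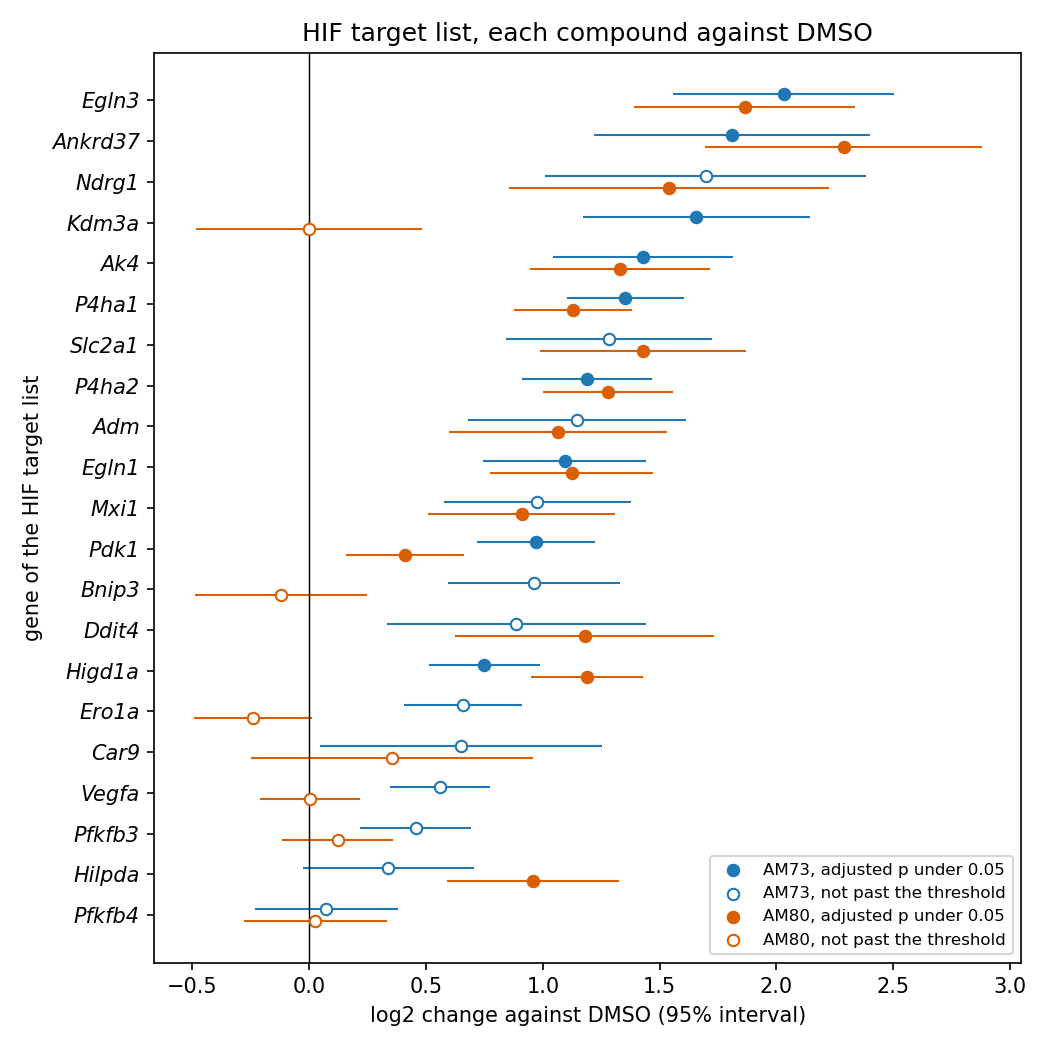
Log2 change against DMSO of the 21 HIF targets with AM73 and with AM80, with 95% intervals from the fit of 9 arrays, filled where the adjusted p is under 0.05. With AM73 9 members passed and with AM80 14, all of them upward.

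AM80 against DMSO asks the same of the second compound, at the same dose and time. It changed 4302 genes in limma, 2130 upward and 2172 downward (1771 and 2209 with arrays centred on their medians, 24 and 24198 under poly-A scaling). Its largest rises include Ucp1 and most of the top genes of AM73. Ankrd37 rose by 2.29 ± 0.26 (adjusted p = 0.00215), Ffar4 by 2.16 ± 0.21 (adjusted p = 0.00191), and Sema3g by 1.98 ± 0.12 (adjusted p = 0.000755). Next came Fosl1 by 1.92 ± 0.18 (adjusted p = 0.00191), Egln3 by 1.86 ± 0.21 (adjusted p = 0.00201), Slc16a3 by 1.81 ± 0.23 (adjusted p = 0.00246) and Smtnl2 by 1.65 ± 0.20 (adjusted p = 0.00217). The largest falls were steeper: the stress protein gene Trp53inp1 (cluster 17411751, chromosome 4, 11156431 to 11174379, −2.84 ± 0.25, adjusted p = 0.00191), the nuclear pore gene Ranbp2 (−2.69), the retinol dehydrogenase gene Dhrs9 (−2.65), and the circadian transcription factor gene Clock (−2.60). They were followed by Dennd10 (−2.56), the nuclear export gene Cse1l (−2.56), Manea (−2.54) and the cohesin regulator Pds5a (−2.48). Each of these passed with any 1 of the 9 arrays left out and with the plate column as a term. The naming rule takes only genes with all 3 AM80 arrays beyond all 3 DMSO arrays, which held for 4251 of the 4302 genes. Of all tested genes 25.5% had groups that did not overlap, where chance gives 10%. Among the DMSO arrays each named fall was lowest on replicate 3, which got no compound (Clock 9.12, 8.83 and 7.58 on replicates 1, 2 and 3). Each named rise but Sema3g was highest there (Ankrd37 4.5, 4.86 and 5.73). These changes thus have the direction in which that array departs, and how much of them comes from AM80 stays open.

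With the plate column as a term 1440 genes passed, 377 higher and 1063 lower, and 73 of the 134 named genes called with AM80 kept their call. Within column 5, 3 AM80 arrays against 1 DMSO array, limma called 0 genes, with 4256 at an unadjusted p under 0.05. The count was 1740 without DMSO replicate 1, 2180 without DMSO replicate 2, 2492 without AM80 replicate 1 and 2482 without AM80 replicate 2. The methods' t-test called 4 genes.

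Called genes that fell with AM80 were longer than those that rose. The median span from the first to the last base of the gene was 44636 bp for genes that fell and 10640 bp for genes that rose, over the 4052 called genes with a span in the reference table. With the genes put into 10 equal bins by span, 135 rose and 20 fell in the shortest bin (median 918 bp). In the longest bin (median 173381 bp) 60 rose and 382 fell. On DMSO replicate 3, compared with the other 2 DMSO arrays, the same called genes showed a rank correlation with span of −0.532, against −0.551 with AM80 and 0.429 with AM73, across genes that are not independent replicates. For Ppargc1a the 2 sources of span differ, with 661605 bp in the reference table and 113477 bp by the array coordinates. By the array coordinates 12 of the 500 tested genes nearest to it in span were as low with AM80, and 19 of 500 among the brighter genes (2 and 5 with the reference table). For Pparg 68 and 96 of 500 were as low, for Esrra 0 and 1 as high, and for Ucp1 0 and 0 as high with either compound. The sets of brighter genes and of array coordinates were added after the first set was seen.

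**Figure D3:**
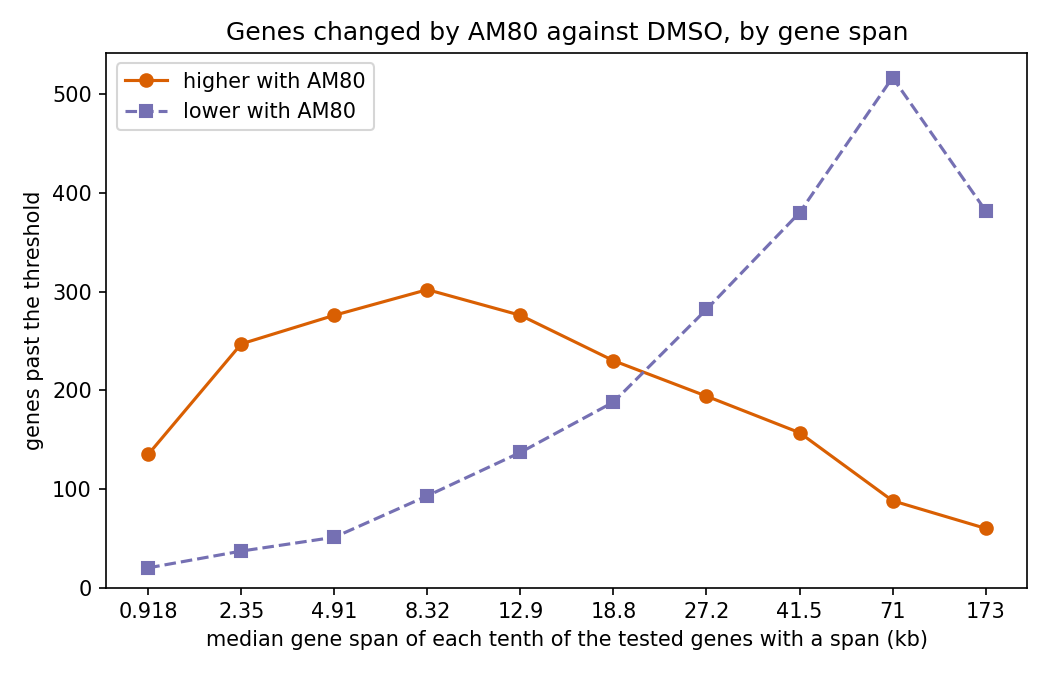
Number of called genes higher and lower with AM80 than with DMSO in each of 10 bins of gene span, labelled with the bin's median span in kb, from the shortest genes to the longest. In the shortest bin 135 are higher and 20 lower, in the longest 60 and 382, and 434 of all 2130 higher genes rose by more than the poly-A shift, while the others would be lower under poly-A scaling.

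Relative to the bulk of genes, camera called upward shifts with AM80 in HIF targets, glycolysis, complex I, complexes II to V and the mitochondrial ribosome (with an estimated correlation the adjusted p = 0.564 for each of these 5 lists). The citric acid cycle, fatty acid oxidation and thermogenic genes were not called (adjusted p = 0.990, 0.0940 and 0.205). HIF targets had a median of 1.07, with 14 of 21 members up and 0 down, both over all genes and adjusted over the list alone (adjusted p = 1.14e-08), and this is the sole list here whose median stays above 0 under poly-A scaling (0.23). Its risers include Higd1a (1.19), P4ha2 (1.28) and P4ha1 (1.13), while Kdm3a, Bnip3 and Vegfa changed by 0.00, −0.12 and 0.00. Glycolysis rose in 11 of 17 members, 13 when adjusted over the list alone (median 0.55, adjusted p = 1.19e-07, −0.29 under poly-A scaling). Among them were Slc2a1 (1.43), Pfkl (1.25) and Pgam1 (1.23). Complex I of the respiratory chain had 19 of 36 members up and 1 down, 24 and 1 when adjusted over the list alone (median 0.44, adjusted p = 2.2e-09, −0.40 under poly-A scaling), with Ndufb8 at 0.85. Complexes II to V had 12 of 38 up and 2 down, 14 and 2 when adjusted over the list alone (median 0.37, adjusted p = 0.000725, −0.48 under poly-A scaling), with Uqcr11 at 1.14. The mitochondrial ribosome had 18 of 39 up and 3 down, 25 and 4 when adjusted over the list alone (median 0.41, adjusted p = 2.16e-05, −0.43 under poly-A scaling), with Mrpl12 at 0.94 and Mrps22 at −0.70.

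AM80 also shifted 3 further lists upward. Immediate early genes, the first to answer growth signals, had 8 of 30 members up and 0 down, 8 and 1 when adjusted over the list alone (median 0.36, adjusted p = 0.000725), with Ier3 at 1.41 and Fosl2 at 0.75. Cytosolic ribosomal proteins had 11 of 33 up and 0 down, 11 and 1 when adjusted over the list alone (median 0.27, adjusted p = 0.00872), with Rps16 at 0.64. PPARγ-driven fat cell genes had 8 of 30 up and 3 down, 18 and 5 when adjusted over the list alone (median 0.32, adjusted p = 0.0128). In the last list Angptl4 (1.38) and Hilpda (0.96), which are also hypoxia-responsive, rose, while the lipid uptake gene Cd36 (−1.43) fell with Pparg itself. With an estimated correlation the adjusted p = 0.564, 0.680 and 0.564, and under poly-A scaling the 3 medians are −0.48, −0.57 and −0.52. All 8 lists kept their calls with the plate column as a term and with the background covariate. Within column 5 all 8 were called as well, but 1 DMSO array stands there and the spread comes from the AM80 arrays, so this adds little. Ribosomal proteins lost their call without DMSO replicate 1 (adjusted p = 0.0634) and with fry (0.0562), and fat cell genes with the filter on dim genes (0.0642). Single members that lost their call included Uqcr11 without DMSO replicate 1 or 2 or AM80 replicate 1 or 2 (adjusted p up to 0.0629) and Rps16 without DMSO replicate 1 or 2 (up to 0.0568), and with the plate column as a term Mrps22 and Rps16 (0.0512 and 0.0578).

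Of these 8 lists 6 hold short genes: complex I, the mitochondrial ribosome, immediate early genes, ribosomal proteins and fat cell genes have median spans of 8097, 7588, 4656, 3551 and 8395 bp, and complexes II to V 6916.5 bp. At such spans called genes mostly rose with AM80 (302 up and 93 down in the bin with a median of 8318 bp, 276 and 51 in that of 4914 bp). Brighter genes of the same span bins had median AM80 changes between 0.16 and 0.17, below each of the 6 list medians. On DMSO replicate 3, compared with the other 2 DMSO arrays, the 6 lists had medians between 0.10 and 0.24, without any compound. The upward shift of these lists thus has the direction of the span trend, and how much of it comes from AM80 stays open. HIF targets and glycolysis hold longer genes (30644 and 22797 bp), with same-span genes at 0.04 for each, and also lay higher on DMSO replicate 3 (0.29 and 0.25).

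**Figure D4:**
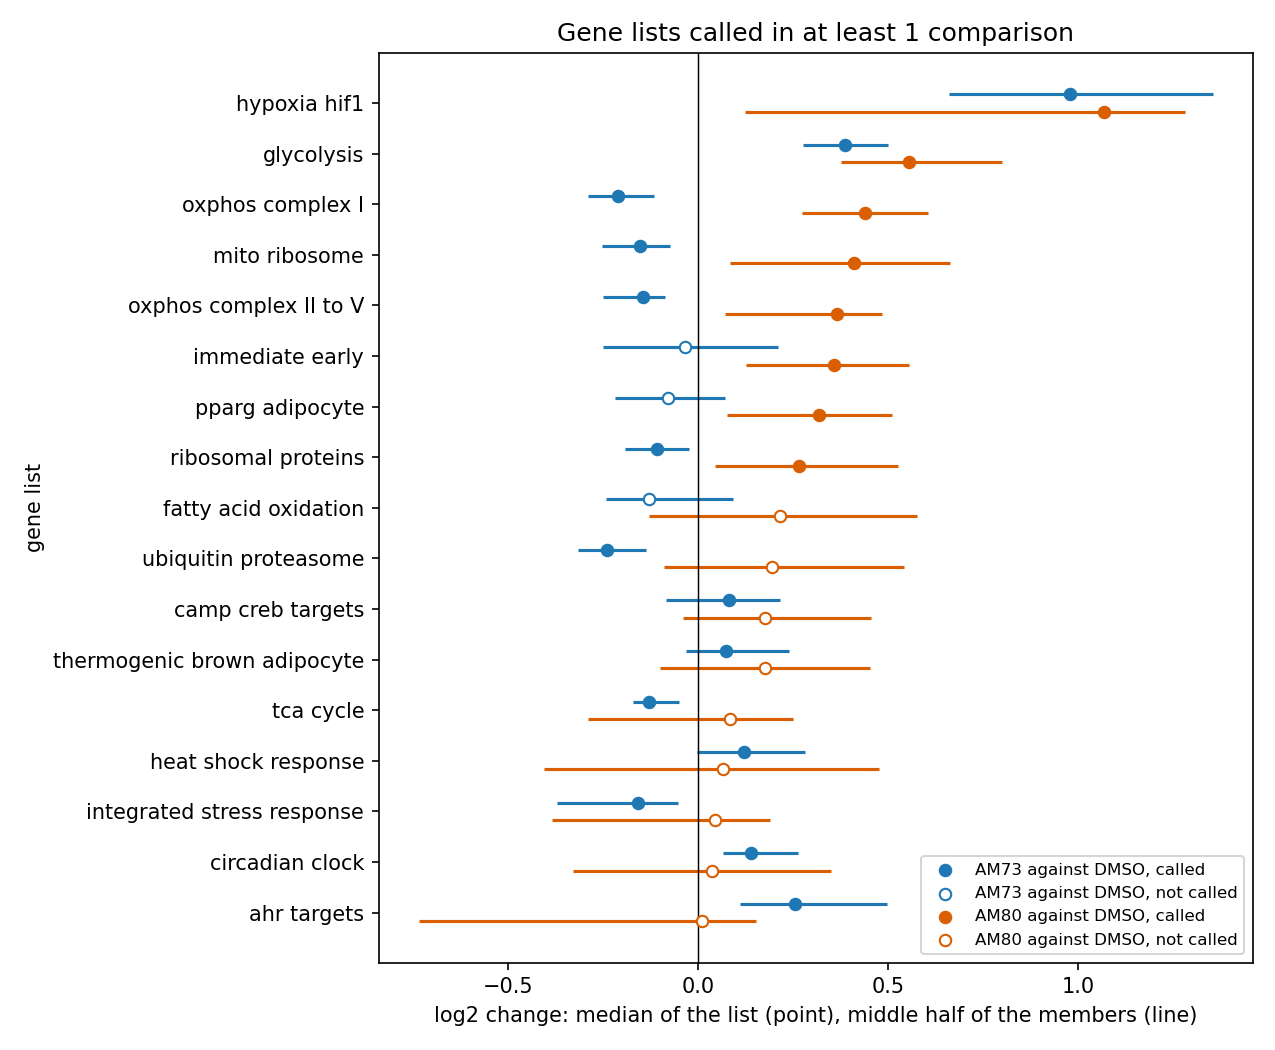
Median log2 change of the members of each gene list called in at least 1 comparison, with bars from the lower to the upper quartile of members, for AM73 and AM80 against DMSO, filled where camera called the list. HIF targets stand highest with both compounds (0.98 and 1.07), respiratory chain lists lie below 0 with AM73 and above 0 with AM80, and under poly-A scaling these signs turn.

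AM80 against AM73 tests directly where the compounds differ at the same dose and time, and it gave the largest gene count of the 3 comparisons. AM80 lay higher for 3061 genes and lower for 2846 (5907 in all). The balance depends on scaling, with 2209 higher and 3215 lower when arrays are centred on their medians, and 7 and 28175 under poly-A scaling. The steepest differences downward, among genes the naming rule takes in, were in Clock (−2.97 ± 0.38, adjusted p = 0.00105), Ranbp2 (−2.86), Trp53inp1 (−2.84) and the mRNA export gene Thoc2 (−2.83). They were followed by Dmxl1 (−2.82), the deubiquitinase gene Usp9x (−2.80), Pgap1 (−2.80) and the Ras regulator Rasa1 (−2.79). Upward, after mt-Tq and among the same genes, came the histone genes H4f16 (1.81 ± 0.21, adjusted p = 0.000864), H1f1 (1.77), H2ac21 (1.71), H4c17 (1.67) and H2ac11 (1.67). No list of histone genes was fixed, so they were not tested as a group. The symbol H4c17 covers 11 clusters, which differed by 0.09 to 1.67, and the brightest of them, taken here, differed most. Further rises were in the adipokine gene Cfd (1.57 ± 0.18, adjusted p = 0.000864), the telomerase RNA gene Terc (1.56) and the mitochondrial tRNA gene mt-Tq (2.49, adjusted p = 0.014). On DMSO replicate 3, which got no compound, each named fall was the lowest of the DMSO arrays (Thoc2 7.53, 7.04 and 6.29 on replicates 1, 2 and 3). Each named rise but H2ac11 and Terc was highest there (H4f16 7.5, 7.79 and 7.92). How much of these differences comes from the compounds stays open. Of the called genes 5877 had groups that did not overlap, against 31.5% of all tested genes and 10% by chance. With the plate column as a term 3513 genes passed. Within column 5, 3 arrays against 1, limma called 0 (5446 at an unadjusted p under 0.05), and the methods' t-test called 1804. With the bright background probes as a covariate limma called 0 genes, with 4572 at an unadjusted p under 0.05. These probes separate the AM80 from the AM73 arrays, so this loss does not show that background accounts for the differences. The mt-Tq call was lost without AM73 replicate 1 or 2 or AM80 replicate 1 (adjusted p up to 0.0620), and with the plate column as a term (0.0545).

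Higher with AM80 than with AM73 lay 8 lists, from the respiratory chain to fat cell and immediate early genes, and each of their medians turns negative under poly-A scaling. Complex I had 29 of 36 members higher and 0 lower, 32 and 1 when adjusted over the list alone (median 0.54, adjusted p = 1.99e-12), with Ndufa2 at 0.93. The mitochondrial ribosome had 25 of 39 higher and 3 lower, 30 and 3 when adjusted over the list alone (0.70, adjusted p = 3.23e-07), with Mrpl14 at 1.23. Complexes II to V had 20 of 38 higher and 1 lower, 24 and 1 when adjusted over the list alone (0.51, adjusted p = 7.9e-06), with Sdhc at 0.74. The proteasome had 19 of 31 higher and 2 lower, 21 and 3 when adjusted over the list alone (0.47, adjusted p = 0.000166), with Psmb3 at 1.21. Ribosomal proteins had 15 of 33 higher and 2 lower, 17 and 2 when adjusted over the list alone (0.49, adjusted p = 0.000585). With an estimated correlation the adjusted p = 0.493 for complex I, the mitochondrial ribosome and the proteasome, and adjusted p = 0.602 for complexes II to V and ribosomal proteins. Fat cell genes had 14 of 30 higher and 4 lower, 20 and 4 when adjusted over the list alone (0.41, adjusted p = 0.0102, and adjusted p = 0.602 with an estimated correlation). Immediate early genes had 7 of 30 higher and 1 lower, 9 and 1 when adjusted over the list alone (0.36, adjusted p = 0.0133, and adjusted p = 0.493 with an estimated correlation). Fatty acid oxidation had 11 of 28 higher and 3 lower, 15 and 4 when adjusted over the list alone (0.35, adjusted p = 0.0279, and adjusted p = 0.493 with an estimated correlation), with Etfb at 1.10. Brighter genes of the span bins of these 8 lists had medians between 0.08 (fatty acid oxidation) and 0.24.

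Lower with AM80 than with AM73 were aryl hydrocarbon receptor targets and, narrowly, HIF targets. Of 8 receptor targets 3 were lower and 0 higher, the same when adjusted over the list alone (median −0.30, adjusted p = 0.0159, and adjusted p = 0.493 with an estimated correlation): Tiparp (−2.37), Cyp1b1 (−2.15) and Nfe2l2 (−0.84). All 3 were lowest among the DMSO arrays on replicate 3, where the list median was −0.17 against the other DMSO arrays. How much of the shift comes from the compounds stays open. The members Cyp1a1, Cyp1a2 and Ahrr lay between 1.96 and 2.8 with DMSO, near the background probe medians, and are weakly measured. Of 21 HIF targets 5 were lower and 2 higher, 6 and 2 when adjusted over the list alone (median −0.10, adjusted p = 0.0413, and adjusted p = 0.603 with an estimated correlation). The lower members include Kdm3a at −1.66, Bnip3 at −1.08, Ero1a at −0.90 and Vegfa at −0.56. The difference was −0.17 for Egln3 and −0.22 for P4ha1 (adjusted p = 0.661 and 0.221). The HIF median was 0.00 with the plate column as a term (adjusted p = 0.220) and −0.01 within column 5 (adjusted p = 0.338). The call was lost without DMSO replicate 1, AM73 replicate 1 or 3, or AM80 replicate 2 or 3 (adjusted p up to 0.113), with the filter on dim genes (0.159) and with fry (0.0697). With the background covariate the median was −0.34 (adjusted p = 0.00077), so its size depends on the fit. The filter on dim genes also ended the calls of receptor targets and fatty acid oxidation (adjusted p = 0.0517 and 0.0956). Fatty acid oxidation lost its call with the plate column as a term (adjusted p = 0.0633), and without AM73 replicate 3 or AM80 replicate 3 (up to 0.0805). Within column 5, with 1 AM73 array and the spread from the AM80 arrays, receptor targets and fatty acid oxidation had an adjusted p of 0.118 each. Receptor targets and the other 7 lists passed with the plate column as a term. With the background covariate immediate early genes and fat cell genes lost their calls (adjusted p = 0.126 and 0.0705).

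Of the 37 genes called with AM73, 28 were called with AM80 in the same direction and 14 differed between the compounds. Cyp1b1 moved in opposite directions, up by 1.31 with AM73 and down by 0.84 with AM80 (adjusted p = 0.00633), as did H2bc4 (−0.82 and 0.43, the second with an adjusted p of 0.0207) and Homer1 (0.85 and −0.44, adjusted p = 0.0404 and 0.0386), a gene outside the naming rule and chosen after its values were seen. The H2bc4 call with AM80 was lost without DMSO replicate 2, AM80 replicate 1 or AM80 replicate 2 (adjusted p up to 0.0821), and the Homer1 call with AM73 in each such fit but that without AM80 replicate 1 (up to 0.192). Its call with AM80 was kept only without DMSO replicate 3 (elsewhere up to 0.143). Cyp1b1 was lowest among the DMSO arrays on replicate 3 (7.5, 7.4 and 7.03 on replicates 1, 2 and 3), the direction of its fall with AM80. Homer1 lost both calls with the plate column as a term (0.0909 and 0.0930) and H2bc4 that with AM80 (0.0542), and under poly-A scaling H2bc4 lies below DMSO with both compounds. Higher with both were 25 genes, and lower with both 3, where independent lists of these sizes would share 2.21 and 0.352. Both comparisons use the same 3 DMSO arrays, which those 2 values leave out, so part of the excess may come from the shared arrays. Across all genes the 2 sets of log2 changes had a Pearson correlation of −0.112 and a Spearman correlation of −0.00727, where simulated unchanged groups with shared controls gave 0.499. The covariance was −0.0110 against 0.0180 simulated, and 50.8% of genes had the same sign against 66.7% simulated. Without DMSO replicate 3 the Pearson correlation was 0.131. The simulation holds independent noise and no effects common to an array. Its values show what shared controls alone give, and the gap to them does not measure how alike the compounds are. Any difference among the 3 groups was called for 5216 genes in the moderated F-test (1988 with the plate column as a term, 3340 without AM80 replicate 1 and 3119 without AM80 replicate 2).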

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

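Of the tests below, those of the plate column, of gene span among called genes and of brighter hybridisation were chosen after the result was seen.

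The poly-A spike-in controls, which no comparison of genes uses, were 0.84 higher with AM80 than with DMSO (all 3 AM80 arrays, at 5.85, 5.44 and 5.20, above all 3 DMSO arrays, at 4.51, 4.63 and 4.83). The two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. They stood out as a signal in features outside the main measurement that differs from the control group. The hybridisation controls differed by −0.03, a share of −0.0397 of the poly-A difference. Quantile normalization removes brightness common to an array, so this value cannot decide on a brighter hybridisation. With the bright background probes as a covariate a share of 0.624 of the median rise of 39 poly-A control features remained (0.73 before, 0.46 after), which leaves a part in the background open. A lower ratio of cell RNA to spike-in, by loss of RNA or by less mRNA per amount of total RNA, may contribute as well and was not tested.

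H2bc4, Homer1 and Cyp1b1 stood out because the compounds moved them in opposite directions against DMSO. AM80 minus AM73 was 1.25 for H2bc4, −1.28 for Homer1 and −2.15 for Cyp1b1, each with an adjusted p of 0.000641 for the difference and all 3 arrays of each compound on either side. With the background covariate the adjusted p of the differences lay between 0.0609 and 0.0648. The rise of H2bc4 with AM80 (0.43) was lost without DMSO replicate 2, AM80 replicate 1 or AM80 replicate 2 (adjusted p up to 0.0821), and under poly-A scaling it turns to a fall, so that H2bc4 then moves alike with both compounds. The calls of Homer1 against DMSO were lost in 8 of 9 fits without an array with either compound (adjusted p up to 0.192 and 0.143). Cyp1b1 was lowest among the DMSO arrays on replicate 3 (7.5, 7.4 and 7.03 on replicates 1, 2 and 3), the direction of its fall with AM80. No explanation was tested for these 3 genes.

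The large number of genes changed by AM80 (4302) followed gene span: among 4052 called genes with a span (94.2%) the rank correlation of the change with span was −0.551, and on DMSO replicate 3, which got no compound, it was −0.532 against the other DMSO arrays. Over 24051 tested genes with a span (77.9%) the values were −0.222 and −0.193, the first between the bounds set beforehand for and against, so the test leaves this undecided. With the plate column as a block the called genes kept a share of 1.01 of their change, all 4302 with the same sign, and 1.04 within column 5. These genes were called for a small spread within groups, from which the column term is estimated. The shares were thus largely set by that choice and cannot weigh on the column. On the first principal component, over all tested genes, DMSO replicate 2 (−22.6) and AM73 replicate 2 (−33.5) of column 5 lay away from the AM80 arrays (31.2 to 74.7). They are single arrays, so a part of the column stays open. GC-dependent background explained a share of 0.185 of the squared changes, and 3 of 100 permutations gave as large a share (−0.208 to 0.230). With single arrays left out the share ran from 0.106 to 0.292, the highest without AM73 replicate 3, so the size of its part stays open. A sample property that acts on long genes, such as RNA integrity, may contribute to the AM80 changes, and an effect of AM80 on long genes stays open, since DMSO replicate 3 shows only that the trend can arise without AM80.

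The rise of HIF targets with both compounds (0.98 and 1.07) was weighed against causes shared by the 2 comparisons. With the background covariate shares of 1.27 (AM73) and 0.905 (AM80) of the list medians remained. Without any 1 DMSO array the lowest share that remained was 0.941. Both values argue against a single control array or the background as the whole source. A response of HIF targets to both compounds is a hypothesis found and tested on the same arrays, and an altered oxygen supply in the treated wells stays open, since it was not tested.

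Other splits of the samples into groups of the same sizes were fitted in the same way. For 3 against 3 the 10 splits are too few for a share under 0.05. With AM73 1 of the 10 splits gave as many genes (37, highest other 0) and 1 as many lists (14, highest other 7). With AM80 1 gave as many genes (4302, highest other 0) and 2 as many lists (8, highest other 8, in the split that puts DMSO replicates 1 and 2 with AM80 replicate 2). Between AM80 and AM73 1 gave as many genes (5907, highest other 0) and 1 as many lists (10, highest other 5). For any difference among the 3 groups 1 of 100 splits drawn from 280, the real one, gave as many genes (5216, highest other 4388). A random split of these arrays thus rarely gives as many. The count cannot tell 3 distinct groups from a difference between AM80 and the rest. As the replicates are called technical, arrays of a group can resemble each other for that reason alone, and the count says nothing about separate samples. The 4 highest of the other splits (4388, 4299, 4268 and 4093) keep the 3 AM80 arrays together, so the main structure lies between these arrays and the rest. The AM80 arrays share the compound, plate column 5 and brighter poly-A controls, which the splits cannot tell apart.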

How the results depend on the processing

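The plate column, each column alone, the background covariate, poly-A scaling, 2 arrays left out and the methods' t-test were chosen after the values were seen. Counts of genes stand in the order AM73, AM80, AM80 against AM73, and any difference among groups.

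The counts of 37, 4302, 5907 and 5216 genes stayed within 1.5 times with the dim filter, all clusters, quantile normalization again, median centring, trend and robust moderation, a fold of at least 1.5 where applied, and 2 arrays left out. With only the groups compared they were 2 and 2086 for the compounds against DMSO, with fewer arrays for the spread. The ordinary linear model gave 4, 1642 and 2431 (any difference), array weights 107 with AM73, the authors' deposited q 3, 5 and 3475, and the methods' t-test 3, 4 and 1804. The plate column as a block gave 18, 1440, 3513 and 1988, the background covariate 11, 2403, 0 (4572 at an unadjusted p under 0.05 in limma) and 980. Poly-A scaling gave 124 (123 higher), 24222 (24 higher), 28182 (7 higher) and 27181, since it moves all genes of an array together. Centring turned the balance between compounds from 3061 higher and 2846 lower to 2209 and 3215. Column 5 alone gave 0, 0, 0 and 0 in limma, with 1772, 4256, 5446 and 4643 at an unadjusted p under 0.05 and single arrays assumed to vary like the AM80 arrays, and column 7 alone 0 with AM73 (1804 unadjusted). Where no reason is given, the cause was not tested.

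List counts of 14, 8 and 10 became 1, 0 and 0 with an estimated correlation (7, 2 and 2 at an unadjusted p under 0.05) and 5, 14 and 22 with fry, and column 5 alone gave 4 with AM73. Ucp1 with AM73 kept its rise of 2.16 and lost its call with only 2 groups (adjusted p = 0.147), the ordinary model (0.282) and the plate column (0.0601), at 2.24 in column 5 (0.843) and at 2.13 in column 7 (0.795), over a range of 0.00558 to 0.843. In column 5 Ucp1 with AM80 was 2.10 (0.321, range 0.00107 to 0.321), and Ppargc1a was −1.79 with AM80 (0.321, range 0.000526 to 0.321) and −1.40 between compounds (0.234). With the background covariate the last was −1.05 (0.136, range 0.000546 to 0.234). The correlation of −0.112 was −0.202 with the dim filter, −0.00727 as Spearman's and −0.274 over genes past the threshold, and it reversed to 0.131 without DMSO replicate 3. The cause was not tested.

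With an array left out the counts ranged from 0 to 37, 1740 to 5226, 4164 to 6453 and 3119 to 5645 genes, and 10 to 16, 7 to 12 and 8 to 11 lists. Ucp1 ranged from 1.92 to 2.46 with AM73, 1.72 to 2.23 with AM80 and −0.43 to 0.01 between compounds, Ppargc1a from −0.44 to −0.12, −1.87 to −1.53 and −1.63 to −1.28, and the correlation from −0.170 to 0.131. The AM73 count was 0 without DMSO replicate 1 (2547 at an unadjusted p under 0.05 in limma), 1 without DMSO replicate 2, 3, 2 and 3 without AM73 replicates 1, 2 and 3, and 2 without AM80 replicate 2.

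The replicate block gave 6 genes with AM73, 2999 with AM80, 5063 between compounds and 3896 for any difference, 14, 8 and 10 lists, and Ucp1 with AM73 at 2.16 (adjusted p = 0.0985). Correlations of residuals between arrays of the same number ran from −0.298 to 0.0682, so the numbers do not pair the samples.

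For single named genes the alternatives fixed beforehand, other than leaving out an array, kept a call in 1380 cases, lost it in 59, gained it in 12 and moved a value without a call in 4. Leaving out an array gave 2250, 342, 5 and 14, and the added alternatives 550, 618, 2 and 19. For single lists the numbers were 82, 46, 20 and 11, then 272, 16, 16 and 33, then 117, 25, 11 and 36. The cases not counted here had no call before or after. Signal over background limits dim genes: the array medians of 2.75 to 2.89 lie above the background probe medians (2.07 to 2.32) and below the 6 brightest background probe sets.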

Other observations

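All lists here were planned, and what follows are values without tests of an explanation. AM80 moved members of many lists both ways without a list call, so that medians near 0 can hold changed members. Over all 30860 tested genes 2130 rose and 2172 fell with AM80, so some called members are to be found in most lists. The list counts were not tested against that share, and several lie near it. Under poly-A scaling the rises among them shrink or turn. Each fall named in this paragraph and the next was, among the DMSO arrays, lowest on replicate 3. For Mki67 the values on DMSO replicates 1, 2 and 3 were 9.26, 8.7 and 8.06, and for Slc7a11 8.52, 8.13 and 7.4. How much of these falls comes from AM80 stays open. Of 32 cell cycle genes 7 rose and 7 fell, with Plk1 up by 0.65 and the proliferation genes Mki67 (−2.22), Top2a (−1.90) and Bub1 (−1.69) down. Of 22 genes of the unfolded protein response 3 rose and 6 fell, the endoplasmic reticulum chaperones Canx (−1.02), Hsp90b1 (−1.01) and Dnajb9 (−1.13) among them, and of 18 heat shock genes 2 rose and 5 fell, with Chordc1 at −1.67. In the integrated stress response 2 of 31 rose and 6 fell, with the cystine transporter gene Slc7a11 (−2.24) and Cth (−1.31), and of 23 p53 targets 2 rose and 4 fell, with Ccng1 at −2.26. Of 25 cholesterol synthesis genes 6 rose and 4 fell (Msmo1 −1.48, Hmgcs1 −1.03). Of 26 mitochondrial biogenesis genes 7 rose and 5 fell, with the protease gene Clpp at 0.77 and the fission gene Dnm1l at −1.86. Adjusted over the list alone, the risers and fallers of these 7 lists numbered 12 and 8, 7 and 8, 6 and 5, 4 and 9, 5 and 6, 12 and 7, and 7 and 6. Their camera adjusted p ran from 0.494 to 0.891, and with an estimated correlation the adjusted p = 0.845 to 0.991.

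With AM80 the NRF2 targets, genes of the oxidative stress defence, had 10 of 27 members up and 2 down, with Cbr3 at 1.16, Ephx1 at 0.82 and Pgd at 0.65 (Cbr3 and Pgd with an adjusted p of 0.0542 and 0.0692 with the plate column as a term), 11 and 5 when adjusted over the list alone (camera adjusted p = 0.137, and adjusted p = 0.564 with an estimated correlation). Retinoic acid targets had 5 of 15 up and 1 down, over all genes and adjusted over the list alone, with the adipokine gene Rarres2 at 1.02 and the receptor gene Rara at 0.74 (adjusted p = 0.166, and adjusted p = 0.564 with an estimated correlation). Of 30 thermogenic genes 6 rose and 2 fell, 8 and 3 when adjusted over the list alone (0.205), of 28 fatty acid oxidation genes 7 and 2, or 10 and 3 (0.0940), and of 31 proteasome genes 7 and 1, or 13 and 2 (0.0581), each with an adjusted p = 0.564 with an estimated correlation. Risers and fallers were 4 and 2 of 19 clock genes, 4 and 3 of 18 cAMP targets, 4 and 4 of 21 citric acid cycle genes, 0 and 3 of 8 aryl hydrocarbon receptor targets, 1 and 3 of 28 autophagy genes (Fnip1 −1.84, Lamp2 −1.25), 4 and 3 of 28 matrix genes, 5 and 2 of 15 glucocorticoid targets, 2 and 3 of 27 interferon genes, 6 and 2 of 28 NF-κB targets, 3 and 1 of 24 lipogenesis genes (Elovl6 −1.33), 1 and 2 of 11 LXR targets, 2 and 2 of 12 mitochondrial antioxidants (Prdx3 −1.21) and 1 and 0 of 16 xenobiotic receptor targets. Adjusted over the list alone, these 13 lists had 5 and 5, 6 and 3, 5 and 6, 0 and 3, 6 and 4, 5 and 3, 5 and 2, 3 and 4, 8 and 3, 3 and 2, 2 and 2, 3 and 2, and 1 and 0. Their camera adjusted p ran from 0.222 to 0.990, and with an estimated correlation the adjusted p = 0.564 to 0.991. Median and mean differed in sign for autophagy, cell cycle, clock, matrix, heat shock, integrated stress, p53, citric acid cycle, lipogenesis and aryl hydrocarbon receptor lists.

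With AM73 the lists without a call had 0 members past the threshold over all genes, except immediate early genes, where 2 of 30 rose, Fosl1 (1.69) among them. The methods' t-test called 3 genes in all with AM73. Between AM80 and AM73 higher and lower members numbered 12 and 8 for the cell cycle, 10 and 6 for cholesterol synthesis, 9 and 2 for lipogenesis, 8 and 2 for NRF2 targets (Gstp1 1.21), 8 and 5 for mitochondrial biogenesis, 7 and 3 for autophagy, 7 and 2 for the citric acid cycle, 6 and 6 for the integrated stress response, 6 and 4 for interferon genes, 5 and 4 for NF-κB targets (Saa3 1.33), 5 and 2 for mitochondrial antioxidants, 4 and 6 for heat shock, 4 and 5 for p53, 4 and 4 for thermogenic genes (Ebf2 −1.27, Zic1 −0.64), 4 and 2 for retinoic acid targets, 4 and 1 for matrix and glycolysis genes, 3 and 2 for glucocorticoid targets, 2 and 6 for the clock, 2 and 3 for cAMP targets, 2 and 1 for LXR targets, 1 and 8 for the unfolded protein response and 0 and 0 for xenobiotic receptor targets. Adjusted over the list alone, and in the same order with matrix before glycolysis, they numbered 14 and 8, 12 and 8, 11 and 3, 9 and 3, 8 and 6, 11 and 5, 9 and 5, 10 and 7, 7 and 5, 6 and 5, 5 and 2, 4 and 7, 6 and 6, 8 and 5, 4 and 2, 6 and 2, 5 and 2, 4 and 2, 3 and 7, 2 and 3, 2 and 1, 3 and 8, and 0 and 0. Their camera adjusted p ran from 0.0999 to 0.976. Over all 30860 tested genes 3061 were higher and 2846 lower, and the list counts were not tested against that share. Most of the higher members would be lower under poly-A scaling, which moves all genes by −1.13.

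Few marker genes of other cells passed. Of 16 macrophage and 12 endothelial markers 0 passed in limma in any comparison, over all genes or adjusted over the list alone. With AM80 against DMSO 2 of 14 preadipocyte and fibroblast markers rose (3 when adjusted over the list alone) and 1 of 15 skeletal muscle markers (1 when adjusted over the list alone). Of 10 white adipocyte markers 2 rose and 1 fell, Hoxc8 by −1.13. Between AM80 and AM73 the higher and lower markers numbered 3 and 0 (Gas6 1.20, S100a4 1.12 and Acta2 0.69), 1 and 0, and 1 and 1 (the Acta2 call was lost in 4 of 9 fits without an array, adjusted p up to 0.105, and with the plate column as a term, 0.0712), and with AM73 against DMSO 0 markers passed in limma.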
